A study of Mus musculus with 16 samples.

How the data were processed

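RNA was measured in 16 libraries from 8 male C57BL/6 mice, an adipocyte and a liver library from each. Per the labels' protocols, fat cells were freed from subcutaneous fat with collagenase and extracted with a lipid tissue kit, livers were extracted with TRIzol, poly-A RNA was enriched and TruSeq libraries were sequenced on a NextSeq instrument. The labels give RNA integrity numbers above 6 for adipose and above 9 for liver RNA. Per the submitters' processing notes, bcl2fastq 2.17, STAR 2.5.2b and featureCounts 1.5.0 were used with the genome build mm10. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited files hold raw counts per gene symbol, 1 library each and not normalized, for 23420 genes. Of these symbols 21737 were placed on GRCm38 with GENCODE M21, used for coordinates only, and 1683 were not placed.

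Total counts were 28560887 to 53716669 per library. Of the count values from 1 to 20, 77.9% were even, with 13036 values of 2 against 2716 of 1, so the counts of low genes are not counts of independent molecules. Intervals for genes near 0 were therefore computed on halved counts, as exact binomial 95% intervals, and an alternative with all counts halved and rounded up was added. The same-group pairs of libraries differed by at least 30.4 chi-square units per degree of freedom, far beyond counting error, so replicate spread and not depth set the precision. The median SE of a log2 change was 0.138 in adipocytes and 0.137 in liver, and 0.232 for the difference between tissues.

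Libraries were grouped by tissue and genotype label as 4 groups of 4. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM scaling, the filterByExpr filter by group, two-sided tests and Benjamini-Hochberg adjusted p under 0.05, for knockout-labelled against wild-type in each tissue separately. The difference between the tissues' genotype effects was tested in a group means model over all 16 libraries. TMM factors were 1.02 to 1.16 in wild-type and 0.898 to 0.984 in knockout-labelled adipocyte libraries, and 0.970 to 1.03 in liver. CPM values are TMM-scaled with their SD, and log2 changes carry their SE. The adipocyte and liver libraries of a number come from the same mouse, per the labels, and their deviations from the group means correlated at -0.0918 to 0.142 (Pearson r across genes).

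Gene lists were fixed before the data were examined, 41 in all. They covered Tribbles genes and partners, mature adipocyte markers, adipocyte-secreted factors, adiponectin assembly, adiponectin receptors and AMPK, fatty acid synthesis, triglyceride synthesis, lipolysis and lipid uptake, cholesterol synthesis, fatty acid oxidation, thermogenic genes, oxidative phosphorylation, insulin and glucose use, gluconeogenesis, lipoprotein assembly and clearance, bile acids, acute phase, xenobiotic metabolism, male-biased and female-biased liver genes, stress response, immediate early genes, inflammation, interferon-stimulated genes, circadian clock, extracellular matrix and cell cycle. The others were markers of macrophages, lymphocytes, granulocytes, endothelium, fibroblasts and progenitors, mural cells, skeletal muscle, epithelium, Schwann cells, red cells, hepatocytes, hepatic stellate cells, cholangiocytes and pancreas. Lists with at least 5 tested members were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry. List scores (mean log2 CPM, prior count 2) were compared by exact two-sided permutation over the 35 splits of the 8 libraries, whose smallest p is 0.0286, with adjustment over the lists of a tissue.

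Genes were named by a rule also fixed in advance. It took Trib1 and Adipoq, then, among called genes with a mean of at least 1 CPM and no overlap between the groups, the 12 largest rises and the 12 largest falls per tissue, or the 5 with the smallest p where fewer than 5 passed, then up to 4 members of each list with the smallest p, and the 8 genes with the smallest adjusted p for the tissue difference. All of these genes were followed through each alternative whose filter kept them. Besides Trib1 and Adipoq these were 177 genes in adipocytes and 167 in liver, among them Eif4a2, Rfc4 and Fetub in both tissues and Zfp949 in adipocytes, which were chosen after their values were seen. St6gal1, Masp1 and Rtp4, also chosen afterwards, were not followed through the alternatives. For an earlier draft a shorter set of list members had been picked by hand, and 7 genes whose calls weakened or turned had been dropped from it. That set was discarded, and the full rule replaced it before the text was written. Of the genes that the rule names, 6 are not reported here by name, for a reason unrelated to their values, and all counts include them. The text names the 3 members with the smallest p for a called list and the 2 for the rest, a number settled with the values in view, and a few members beyond these.

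Alternatives fixed in advance were DESeq2 1.42.0 with its own size factors and filtering, limma-voom, DESeq2-style (RLE) size factors, library totals alone, no filter, a filter of 1 CPM in at least 4 libraries, an adjusted p under 0.1, an age term, the mice taken at 76 days alone, all 16 libraries in a shared fit, leaving out each mouse in turn, and, for the tissue difference, the mouse as a fixed or a random block. Halved counts and a covariate of endothelial, fibroblast and mural scores were added after the data were seen. The steps were tested on simulated counts with 100 genes changed at each of 2 sizes: edgeR recovered 32% of 1.5-fold and 73% of 2-fold changes in adipocytes with 4 false calls, 41% and 75% in liver with 6, and 11% and 42% for the tissue difference with 0. DESeq2 made 36, 22 and 17 false calls in the same simulations. A list of 47 genes planted at 1.3-fold was called in both tissues with preset (adjusted p = 1.06e-48 and 1.8e-42) and estimated correlation (0.000172 and 0.000105), and with the preset 1 other liver list was also called. The simulated genes were drawn independently of each other, whereas the oxidative phosphorylation list in adipocytes had an estimated correlation of 0.772. The simulation therefore cannot show how either list test behaves for correlated genes. No sample was left out.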

Results

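The series profiled polyadenylated RNA in 8 male C57BL/6 mice, 4 labelled wild-type and 4 labelled as carrying an adipocyte-specific knockout of Trib1, the gene for the pseudokinase tribbles 1. Each mouse gave a library of collagenase-isolated subcutaneous adipocytes and a library of whole liver, so the 16 libraries form 4 groups of 4. Total counts per library ran from 28560887 to 53716669, and between 15279 and 16747 genes had counts in a library. A count of 0 in a library allows up to 3 counts, a level of 0.0558 to 0.105 CPM (counts scaled by library total) depending on the library. This limit covers counting error only, and low counts were mostly even numbers, so it is too low where reads were counted in pairs. The wild-type mice, named by label and number, were WT-1135, WT-1136, WT-1138 and WT-1153, and the knockout-labelled mice were KO-1137, KO-1139, KO-1151 and KO-1152. Mice KO-1151, KO-1152 and WT-1153 were taken at 70 days and the others at 76 days, so both ages held both genotypes.

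Trib1 itself did not separate the genotype labels in either tissue. The files list it as Trib1, and the annotation places it on chromosome 15 from 59648350 to 59657099 on the plus strand of GRCm38. In adipocytes Trib1 reached 752 to 1293 CPM in the wild-type libraries and 1071 to 1408 CPM in the knockout-labelled ones, a log2 difference of 0.28 ± 0.18 (SE, n = 4 per group; edgeR adjusted p = 0.241). In liver the difference was 0.12 ± 0.18 (n = 4 per group; edgeR adjusted p = 0.875), at 59.8 ± 8.89 CPM (SD) in wild-type and 64.9 ± 16.3 CPM in knockout-labelled libraries. The labels name neither the deleted part of Trib1 nor the driver of the deletion, and a gene total also counts reads from exons that a deletion leaves in place. Every direction given here is therefore that of the libraries labelled knockout against those labelled wild-type. Adipoq, which encodes the adipocyte hormone adiponectin and lies on chromosome 16 from 23146536 to 23158028, did not pass the test in adipocytes, with a log2 difference of 0.41 ± 0.15 (n = 4 per group; edgeR adjusted p = 0.0548). Its CPM values did not overlap between the groups, with 2735 to 4093 in wild-type and 4469 to 5028 in knockout-labelled libraries. The Adipoq difference passed with DESeq2 (adjusted p = 0.0114) and with limma-voom (adjusted p = 0.0431). With library totals alone it was at 0.22 and did not pass (edgeR adjusted p = 0.154). In the fit of all 16 libraries, whose spread takes in liver, it was at 0.43 ± 0.5 (edgeR adjusted p = 0.542). There the estimate was kept and its SE grew. With a covariate of stromal markers, chosen after the data were seen, the Adipoq difference was at 0.0284 (adjusted p = 0.974). Adipoq was not tested in liver, where the libraries held 0 to 90 counts of it.

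**Figure D1:**
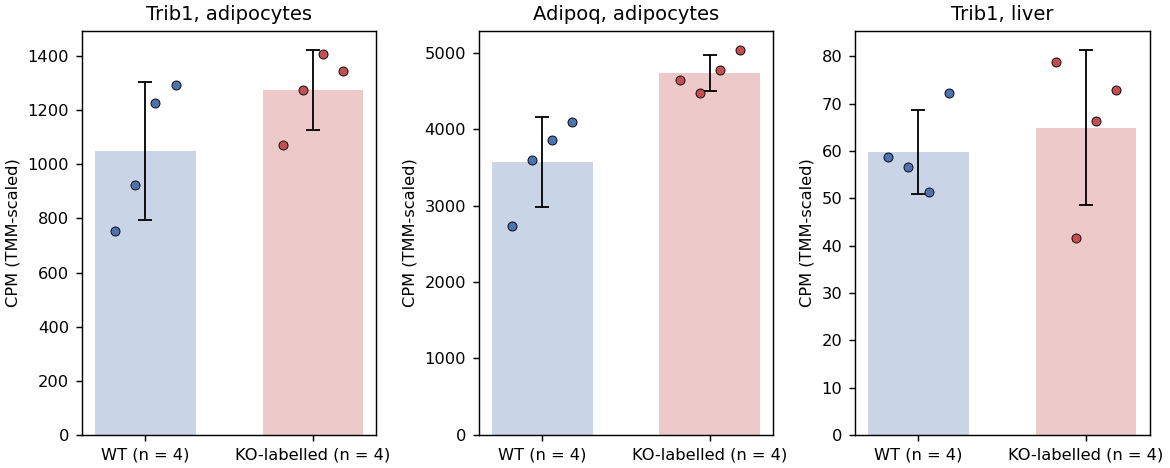
Trib1 in adipocytes and liver and Adipoq in adipocytes, as TMM-scaled CPM for each library (points), with group means (bars) and SD (lines), n = 4 per group. The adipocyte Trib1 values overlap between 752 to 1293 in wild-type and 1071 to 1408 in knockout-labelled libraries.

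In adipocytes of knockout-labelled mice most listed genes of oxidative phosphorylation, triglyceride synthesis and cholesterol synthesis rose, and most interferon-stimulated genes and markers of endothelial, mural and fibroblast cells fell. Camera called these lists with its preset correlation, and 0 lists with an estimated correlation. The largest fall was that of Cyp2f2, a cytochrome P450, from 263 ± 43.7 to 1.11 ± 0.148 CPM (SD, n = 4 per group). Slc15a5, a member of the peptide transporter family, rose from 0.909 ± 0.25 to 50.7 ± 18.1 CPM, and Elovl4, an elongase of very long fatty acids, rose from 0.518 ± 0.192 to 15.8 ± 4.4 CPM. The edgeR test called 4849 of 13795 genes (35.2%), 2487 higher and 2362 lower in the knockout-labelled libraries, and 477 of these were at least 2-fold higher and 1391 at least 2-fold lower. The counts of called list members below are to be read beside this share, which several lists do not exceed. The groups did not overlap for 4674 genes, 33.9% of those tested, where chance gives 2.86%. Scaling by library totals alone moved the median log2 change of all genes by -0.193 and gave 1293 higher and 3899 lower genes, 24.9% higher in place of 51.3%. Small list medians, such as 0.217 for adipocyte markers and 0.243 for stress response genes, are close to this shift in size.

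The 12 largest rises past the test included genes with almost no counts in wild-type libraries. Rasef had 0 counts in the 4 wild-type libraries and 762 in the knockout-labelled ones, and no fold is given for it. Cyp2b9, a cytochrome P450, had 4 against 1091 counts, a ratio of 289 (95% exact interval 79.6 to 2390, computed on halved counts). The ratio was 67.1 (32.3 to 168) for Aadac, a triglyceride-associated deacetylase, 68.9 (33.2 to 172) for Acot5, a peroxisomal acyl-CoA thioesterase, and 33.7 (16.9 to 79) for Chodl. For Acot3 the ratio was 20.1 (10.3 to 44.7), and for the falling gene Ngfr it was 0.206 (0.0773 to 0.469). These intervals cover counting error only, not the spread between mice. Log2 rises were 8.91 ± 0.31 for the gene model Gm9696, 5.80 ± 0.31 for Slc15a5, 5.52 ± 0.43 for the lysophosphatidic acid receptor Lpar3, 5.26 ± 0.32 for the kininogen gene Kng2, 5.19 ± 0.32 for Shisa6, 4.93 ± 0.65 for the BMP receptor Bmpr1b and 4.92 ± 0.30 for Elovl4, with edgeR adjusted p between 7.48e-07 and 0.000738. Of these, Gm9696 and Bmpr1b had wild-type means of only 0.127 and 0.148 CPM, and no interval was computed for them. The 12 largest falls had edgeR adjusted p between 2.37e-08 and 0.0014. Cyp2f2 fell by 7.89 on the log2 scale, and the imprinted genes H19 (-4.78) and Nnat (-4.23) fell as well. H19 averaged only 0.128 CPM in the knockout-labelled libraries, and no interval was computed for it. The fatty acid transport protein gene Slc27a2 fell by 3.32, and Cyp1a1, a target of the aryl hydrocarbon receptor, fell by 3.23. The other falls were Spon1 (-3.78 ± 0.48), Gm4841 (-3.71 ± 0.48), Tbc1d16 (-3.51 ± 0.24), Slc26a10 (-3.29 ± 0.42), the interferon target Ifit1 (-3.12 ± 0.38), Prtn3 (-3.01 ± 0.27) and the potassium channel gene Kcnh2 (-2.95 ± 0.25). With the covariate of stromal markers some of the 12 largest rises and falls kept their direction but no longer passed in edgeR. These were Cyp1a1 (-1.29, adjusted p = 0.394), Slc26a10 (-1.36, 0.183), H19 (-3.32, 0.123), Chodl (4.82, 0.123), Acot5 (5.22, 0.0709) and Bmpr1b (4.27, 0.053). The rest of the 12 largest rises and falls kept their calls.

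**Figure D2:**
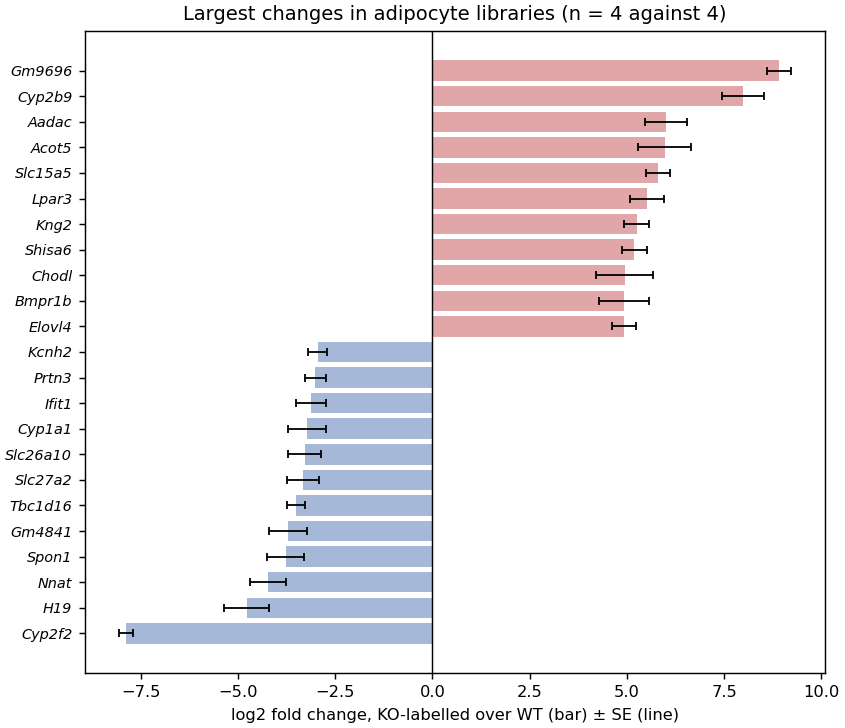
Log2 fold change (bar) and its SE (line) in adipocytes, knockout-labelled over wild-type (n = 4 per group), for the genes with the largest rises and falls past the test. Rasef is left out because its wild-type counts were all 0, and the bars run from -7.89 for Cyp2f2 to 8.91 for Gm9696.

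Most oxidative phosphorylation genes, and part of further lists of energy metabolism, rose in the knockout-labelled adipocyte libraries. Of 47 nuclear-encoded subunits of oxidative phosphorylation, 45 rose and 0 fell, by edgeR (46 higher when adjusted over the list alone), with a median log2 change of 0.55, among them Atp5o (0.75 ± 0.10), Uqcrfs1 (0.77 ± 0.11) and Sdhd (0.72 ± 0.11). The camera adjusted p for this list was 1.09e-16 with the preset correlation, and adjusted p = 0.439 with an estimated correlation. In fatty acid oxidation 14 of 27 genes rose and 2 fell (14 and 2 adjusted over the list alone), with the mitochondrial dehydrogenase gene Acadvl at 0.92 ± 0.10 and the thioesterase gene Acot2 at 0.97 ± 0.15 higher (camera adjusted p = 0.0025, and adjusted p = 0.459 with an estimated correlation). In insulin signalling and glucose use 8 of 17 genes rose and 0 fell (9 higher adjusted over the list alone), including Tbc1d4 (0.99 ± 0.13), Pfkl (0.82 ± 0.13) and the glycogen synthase gene Gys1 (0.68 ± 0.11). For this list camera gave adjusted p = 0.0027, and adjusted p = 0.439 with an estimated correlation. In gluconeogenesis 5 of 7 rose (7 adjusted over the list alone), including Gpt (0.55 ± 0.10), Pck1 (0.74 ± 0.15) and Pcx (0.72 ± 0.16). The list had camera adjusted p = 0.00513, and adjusted p = 0.439 with an estimated correlation. The mean score of endothelial, fibroblast and mural markers was lower in the same libraries by a log2 difference of -1.45 (exact permutation p = 0.0286, n = 4 per group, the smallest such a test can give). With that score as a covariate, chosen after the data were seen, the median of oxidative phosphorylation genes was 0.301 and 0 of them were called. The medians of fatty acid oxidation (0.365 to 0.0612) and of insulin signalling and glucose use (0.4 to -0.00574) went to near 0, that of gluconeogenesis went from 0.644 to 0.508, and 0 genes of these lists were called.

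Most triglyceride and cholesterol synthesis genes, and part of other lipid lists, rose in the same libraries, in which that marker score was lower. With the covariate 1 triglyceride synthesis gene and 0 cholesterol synthesis genes were called, and their medians went from 0.642 to 0.326 and from 0.456 to 0.427, the latter with a median SE of 0.286 in place of 0.154. For adipocyte markers the median went from 0.217 to 0.0207 and for lipolysis and lipid uptake from 0.279 to 0.135, with 0 genes called in either list. Of 15 triglyceride synthesis genes 10 rose and 0 fell (10 adjusted over the list alone), among them the acyltransferase genes Mogat2 (2.39 ± 0.27), Agpat1 (0.50 ± 0.08) and Agpat9 (1.14 ± 0.19). Their camera adjusted p was 0.000191, and adjusted p = 0.439 with an estimated correlation. In lipolysis and lipid uptake 9 of 20 rose and 3 fell (10 and 3 adjusted over the list alone): the lipase activator gene Abhd5 (1.05 ± 0.12) and the fatty acid binding gene Fabp5 (1.39 ± 0.19) rose, while Gpihbp1, which anchors lipoprotein lipase on capillary endothelium, fell by 1.63 (camera adjusted p = 0.0118, and adjusted p = 0.453 with an estimated correlation). Of 25 cholesterol synthesis genes 14 rose and 0 fell (15 and 1 adjusted over the list alone), including Cyp51 (1.54 ± 0.26), Hmgcs1 (0.87 ± 0.15) and Nsdhl (0.63 ± 0.12). The camera test gave adjusted p = 0.00213, and adjusted p = 0.461 with an estimated correlation. Of 24 mature adipocyte markers 6 rose and 1 fell (the same counts adjusted over the list alone), with Retn, which encodes resistin, at 1.27 ± 0.14, Pparg, the adipogenic nuclear receptor, at 0.40 ± 0.08, and Sncg at -1.0 ± 0.18 (camera adjusted p = 0.0104, and adjusted p = 0.499 with an estimated correlation). Pparg did not pass in edgeR with library totals (0.21, adjusted p = 0.0616) or in the mice taken at 76 days (0.121). Nor did it with all 16 libraries in the fit (0.128) or with the covariate (0.396). In de novo fatty acid synthesis and desaturation 4 of 18 rose and 2 fell (the same counts adjusted over the list alone), with Me1 higher (1.04 ± 0.20) and the desaturase gene Fads1 lower (-1.87 ± 0.13), and the list was not called (camera adjusted p = 0.442).

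Genes best known from liver and stress responses also moved, again beside the lower marker score. With the covariate acute phase calls went from 13 to 1 (median 1.16 to 0.564), stress response calls from 8 to 2 (0.243 to 0.0723) and male-biased calls from 8 to 3 (2.71 to 1.43). For female-biased genes they went from 5 to 3 (1.96 to 3.03), and for hepatocyte markers from 6 to 3 (0.269 to 0.085). Of 16 acute phase genes 12 rose and 1 fell (the same counts adjusted over the list alone), including Saa3 (2.63 ± 0.20), the haptoglobin gene Hp (1.53 ± 0.18) and Lcn2 (1.58 ± 0.19). By camera the list had adjusted p = 2.31e-07, and adjusted p = 0.439 with an estimated correlation. Of 11 tested genes known as male-biased in liver 8 rose and 0 fell (9 and 1 adjusted over the list alone), with Mup3 at 3.59 ± 0.25, the complement gene C6 at 3.88 ± 0.29 and the elongase gene Elovl3 at 4.49 ± 0.46. Further, 3 of 6 known as female-biased rose and 2 fell (the same counts adjusted over the list alone), led by Cyp2b9, Acot3 (4.28 ± 0.47) and Cyp2b13. Camera gave adjusted p = 2.09e-08 and 0.0097 for these lists, and adjusted p = 0.155 and 0.439 with an estimated correlation; the female-biased call was lost without mouse WT-1136 (adjusted p = 0.0529). For Cyp2b13 the libraries held 2 against 108 counts, a ratio of 57.1 (9.83 to 2300). Hepatocyte markers went both ways, with 5 of 11 higher and 1 lower (the same counts adjusted over the list alone): Mup3 and the fibrinogen gene Fga (2.48 ± 0.46) rose, and the albumin gene Alb fell by 1.88 (camera adjusted p = 0.0434, and adjusted p = 0.514 with an estimated correlation). The hepatocyte call was lost without mice WT-1135, WT-1136, WT-1138, KO-1139, KO-1151 or KO-1152, at adjusted p up to 0.27. Major urinary protein (Mup) genes and the Cyp2b genes are near-identical families among which reads can be shared, so their separate values are uncertain. Of 20 unfolded protein and integrated stress response genes 8 rose and 0 fell (9 and 2 adjusted over the list alone), including Chac1 (1.75 ± 0.20), Edem1 (0.64 ± 0.08) and Atf5 (0.59 ± 0.08). The list was called at camera adjusted p = 0.00495, and adjusted p = 0.439 with an estimated correlation.

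Interferon-stimulated genes fell in the knockout-labelled adipocyte libraries, in which the marker score of endothelial, fibroblast and mural cells was also lower. With that score as a covariate 6 interferon genes were called in place of 19, and 0 inflammatory genes in place of 8. The inflammatory median stayed at -0.39 against -0.472, with a median SE of 0.577 in place of 0.355, while the matrix median moved from -0.77 to 0.0798. The matrix list shares Col1a1 and Col3a1 with the fibroblast list of that score, so part of its move is built in. Immediate early calls went from 7 to 2 (median -0.287 to -0.195), and lymphocyte marker calls from 8 to 0 (-1.09 to 0.0613). Of 25 interferon-stimulated genes, 19 fell and 0 rose (20 lower adjusted over the list alone), with a median log2 change of -1.17, among them Ifi27l2a (-2.17 ± 0.19), Mx2 (-2.36 ± 0.24) and the transcription factor gene Irf7 (-0.73 ± 0.08). Camera gave adjusted p = 1.33e-10, and adjusted p = 0.439 with an estimated correlation. Of 23 inflammatory genes 7 fell and 1 rose (the same counts adjusted over the list alone), with the adhesion genes Vcam1 (-1.24 ± 0.17) and Icam1 (-1.27 ± 0.24) and the nitric oxide synthase gene Nos2 (-1.92 ± 0.39) lower. This list had camera adjusted p = 0.0118, and adjusted p = 0.453 with an estimated correlation. Of 26 immediate early and dissociation genes 7 fell and 0 rose (the same counts adjusted over the list alone), including Egr3 (-1.48 ± 0.25), Junb (-0.76 ± 0.15) and Nr4a1 (-0.59 ± 0.13). These had camera adjusted p = 0.00942, and adjusted p = 0.492 with an estimated correlation. Of 24 extracellular matrix genes 12 fell and 1 rose (13 and 1 adjusted over the list alone): the proteoglycan gene Bgn (-2.41 ± 0.25) and the collagen gene Col6a3 (-1.95 ± 0.21) fell, and the collagen cross-linking gene Lox rose (1.48 ± 0.26). For matrix genes camera gave adjusted p = 0.00213, and adjusted p = 0.461 with an estimated correlation.

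Markers of other cell types were lower in the knockout-labelled adipocyte libraries for several lists. Endothelial markers fell for 18 of 19 genes (18 adjusted over the list alone), with a median of -1.86, including Ptprb (-1.87 ± 0.30), Emcn (-1.95 ± 0.32) and the VEGF receptor gene Kdr (-1.88 ± 0.32). Pericyte and smooth muscle markers fell for 11 of 12 (12 adjusted over the list alone), with a median of -1.43, including Abcc9 (-2.27 ± 0.21), Mylk (-0.92 ± 0.13) and Acta2 (-1.59 ± 0.35). Fibroblast and progenitor markers fell for 12 of 20 (14 adjusted over the list alone), with a median of -1.36, including Lum (-1.47 ± 0.20), Ly6c1 (-1.77 ± 0.30) and Dpt (-0.82 ± 0.17). Lymphocyte markers fell for 8 of 23 (8 adjusted over the list alone), including Cd5 (-2.59 ± 0.56), Cd4 (-0.91 ± 0.27) and Lck (-1.42 ± 0.42). The list of hepatic stellate markers, which shares fibroblast genes such as Dcn, fell for 5 of 10 (7 adjusted over the list alone), including Cygb (-1.52 ± 0.29), Ngfr (-2.20 ± 0.46) and Pdgfrb (-1.59 ± 0.39). Of 21 macrophage markers only Cd14 fell (-1.3 ± 0.15, also when adjusted over the list alone), and Ctss (-0.78 ± 0.39) and Itgax (-0.71 ± 0.51) did not pass. Camera adjusted p was 2.02e-09 for endothelial, 2.91e-05 for mural, 2.41e-05 for fibroblast, 0.000643 for lymphocyte, 0.0097 for stellate and 0.0436 for macrophage lists. For the same lists in that order adjusted p = 0.439, 0.439, 0.439, 0.526, 0.453 and 0.64 with an estimated correlation. The macrophage call was lost without mice WT-1135, WT-1136, KO-1139 or KO-1152, at adjusted p up to 0.146. By exact permutation of list scores (n = 4 per group), the endothelial, mural, stellate and skeletal muscle scores were lower at p = 0.0286, the smallest possible, and adjusted p = 0.046. That adjusted p depends on how many of the 37 lists share the smallest p, and 23 lists passed with it. A pass or its loss is therefore no measure of the size of a difference. The endothelial, mural, stellate and skeletal muscle scores did not pass with medians in place of means, where the differences were -1.79, -1.75, -0.991 and -0.825 in that order. Likewise 0 marker scores passed when any of 7 of the 8 mice was left out.

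**Figure D3:**
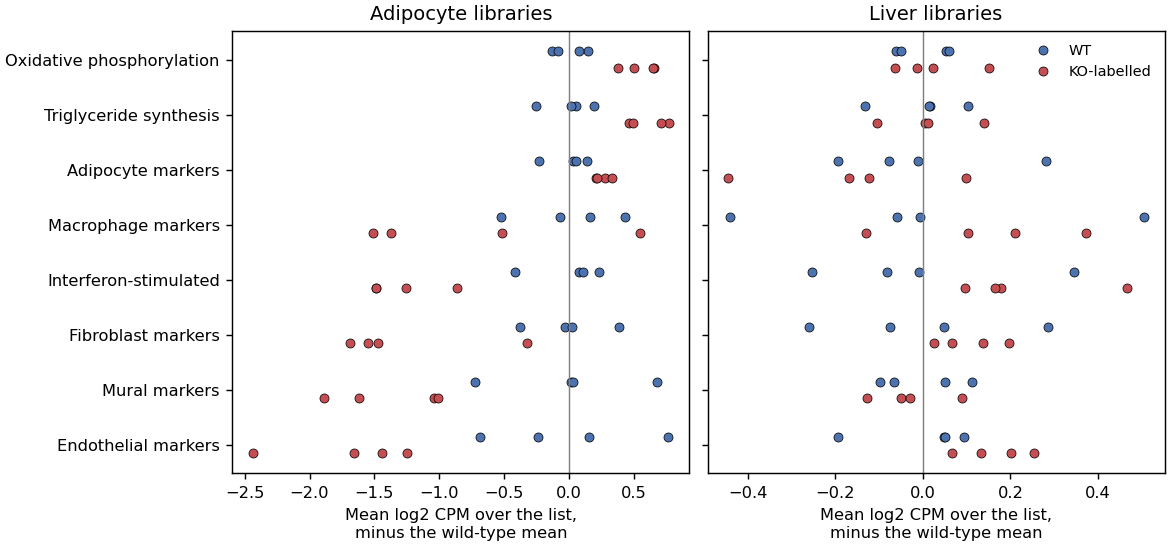
Mean log2 CPM over each gene list for every library, minus the wild-type mean of that tissue, in adipocyte (left) and liver (right) libraries, n = 4 per group. In adipocytes the oxidative phosphorylation score was higher by 0.55 and the endothelial score lower, at -1.70, in knockout-labelled libraries.

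Across the 41 lists, 37 held enough tested genes in adipocytes, and camera with its preset correlation called 13 higher and 10 lower, while 0 were called with an estimated correlation, where the lowest adjusted p was 0.155. Fry called 27 of the 37, without the macrophage (adjusted p = 0.191) and lymphocyte lists (adjusted p = 0.0523). Fry asks whether the members themselves move, not whether they move more than other genes. With 35.2% of all tested genes called, many lists can pass it. With the marker score of endothelial, fibroblast and mural cells as a covariate, an alternative chosen after the data were seen, edgeR called 437 genes and camera 6 lists, and the score itself was strongly correlated with genotype, with a squared correlation of 0.748. In the 5 mice taken at 76 days edgeR called 1730 genes.

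Liver differed far less between the genotype labels than adipocytes did. Zfp949, a zinc finger gene, rose from 7.81 ± 1.26 to 26.2 ± 2.85 CPM (SD, n = 4 per group), a log2 change of 1.75 ± 0.13 (edgeR adjusted p = 0.000518). The neighbouring kininogen genes Kng1 and Kng2, which encode precursors of bradykinin, rose by 0.85 ± 0.11 (edgeR adjusted p = 0.0469) and 0.71 ± 0.09 (edgeR adjusted p = 0.04), from 2799 ± 296 to 5061 ± 267 CPM and from 285 ± 16.6 to 466 ± 32.9 CPM. These 3 genes were all that edgeR called among 13288, with 0 lower, while 1146 genes had an unadjusted p under 0.05, DESeq2 called 55 higher and 47 lower, and limma-voom called 3. Higher without passing were Elovl6, an elongase of fatty acid synthesis (1.02 ± 0.15), and the phospholipase gene Ddhd2 (0.67 ± 0.10), both at edgeR adjusted p = 0.0989. DESeq2 called both, Elovl6 passed in edgeR without a filter (adjusted p = 0.0397) and Ddhd2 with all 16 libraries in the fit (adjusted p = 0.0269). The 5 lower genes with the smallest p did not pass: the adenosine receptor gene Adora1 (-1.16 ± 0.18), the aldehyde oxidase gene Aox1 (-0.71 ± 0.11), the chloride channel gene Clcn2 (-0.46 ± 0.08), 9130409I23Rik (-1.40) and Robo1 (-1.46 ± 0.27). DESeq2 called all 5, at adjusted p from 2.33e-06 for Adora1 to 0.00089 for Clcn2. Adora1 also passed in edgeR with an age term (adjusted p = 0.00347), without a filter (0.0456) and with all 16 libraries in the fit (0.0245). Groups did not overlap for 619 genes, 4.66% of those tested, where chance gives 2.86%. Zfp949 was called without each mouse in turn, whereas Kng1 and Kng2 were each called without WT-1136 alone and lost without WT-1135, KO-1137, WT-1138, KO-1139, KO-1151, KO-1152 or WT-1153, at adjusted p of 0.0688 to 0.193. With an age term both were lost, at adjusted p of 0.084 for Kng1 and 0.0674 for Kng2. In the fit of all 16 libraries they were lost at 0.637 and 0.156, and with halved counts Kng1 was lost at 0.0527. Their log2 changes in these fits stayed at 0.84 to 0.86 for Kng1 and 0.70 to 0.71 for Kng2. In the mice taken at 76 days edgeR called 0 genes, with Zfp949 at adjusted p = 0.0501.

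In liver the main edgeR fit called no list member over all genes, so the lists are described by their shared shift. DESeq2 called several, among them Elovl6 (adjusted p = 5.45e-07), Acot1 (0.000273), Acacb (0.0012), Gsta2 (0.00229) and Cyp4a31 (0.00264). Camera with its preset correlation called 7 lists higher and 1 lower of 38, and 0 with an estimated correlation. Fatty acid oxidation genes had positive changes for 25 of 29 (5 higher adjusted over the list alone), with Acot1 at 0.85 ± 0.15, the PPAR-alpha target Cyp4a31 at 1.0 ± 0.22 and Plin2 at 0.67 ± 0.17 (camera adjusted p = 3.79e-07, and adjusted p = 0.5 with an estimated correlation). Xenobiotic genes were the list called lower, with positive changes for 3 of 18 (2 lower adjusted over the list alone), the glutathione transferase genes Gsta2 at -1.10 ± 0.24 and Gsta1 at -2.03 ± 0.49, and Cyp3a11 at -0.37 ± 0.12 (camera adjusted p = 5.49e-05, and adjusted p = 0.16 with an estimated correlation). Male-biased genes were positive for 18 of 22 (0 adjusted over the list alone), with Slco1a1 at 0.40 ± 0.11, Ugt2b38 at 1.12 ± 0.46 and Mup2 at 1.04 ± 0.44 (camera adjusted p = 0.000216, and adjusted p = 0.787 with an estimated correlation). Interferon-stimulated genes were positive for 21 of 25 (0 adjusted over the list alone), with Oasl2 at 0.52 ± 0.15, Stat2 at 0.28 ± 0.11 and Gbp2 at 0.46 ± 0.19. Fatty acid synthesis genes were positive for 14 of 19 (2 higher and 1 lower adjusted over the list alone), with Elovl6, Acacb at 0.82 ± 0.16 and Srebf1, the lipogenic transcription factor gene, at -0.49 ± 0.14. Camera gave adjusted p = 0.000492 for interferon and 0.000597 for fatty acid synthesis, and adjusted p = 0.787 for both with an estimated correlation. The interferon call was lost without KO-1139 (adjusted p = 0.0634) and the synthesis call without KO-1151 (adjusted p = 0.0534).

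The remaining liver calls were small shifts. Endothelial markers were positive for 16 of 18 (0 adjusted over the list alone), with Flt1 at 0.52 ± 0.18, Egfl7 at 0.29 ± 0.10 and Pecam1 at 0.23 ± 0.11 (camera adjusted p = 0.00391, and adjusted p = 0.787 with an estimated correlation), and this call was lost without WT-1136 (adjusted p = 0.116). Cholesterol synthesis genes were positive for 17 of 26 (3 higher adjusted over the list alone), with Hsd17b7 at 0.54 ± 0.11 and Sqle at 0.73 ± 0.20. Macrophage markers were positive for 14 of 21 (1 higher adjusted over the list alone), with the scavenger receptor gene Msr1 at 0.53 ± 0.11 and Cd163 at 0.42 ± 0.19. Both had camera adjusted p = 0.048, and adjusted p = 0.855 and 0.867 with an estimated correlation. Cholesterol synthesis was lost without WT-1136, WT-1138, KO-1139 or KO-1151 (adjusted p up to 0.524), and macrophage without WT-1135, WT-1136, KO-1137, KO-1151, KO-1152 or WT-1153 (up to 0.941). The other 30 tested lists were not called, at camera adjusted p from 0.0938 for granulocyte markers to 0.995 for acute phase genes, among them lipoprotein assembly and clearance (0.582), with Angptl4 at 0.43 ± 0.11 and Abcg8 at -0.37 ± 0.10, and bile acid genes (0.179), with Cyp8b1 at -0.80 ± 0.19 and Cyp2c70 at 0.51 ± 0.13. Fry, which asks whether a list moves to one side, called 0 liver lists.

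Kng1 and Kng2 lie next to Adipoq on chromosome 16. Kng2 spans 22985854 to 23029482 and Kng1 23057865 to 23082078, followed by Eif4a2 (23107444 to 23114136), Rfc4 (23113943 to 23127737) and Adipoq. In liver Eif4a2, a translation initiation factor gene chosen after its values were seen, was at 0.51 ± 0.08 without passing in edgeR (adjusted p = 0.139). Its liver CPM values did not overlap between the groups. Rfc4, likewise chosen afterwards, was at 0.04 ± 0.18 in liver and 0.51 ± 0.21 in adipocytes, and passed in neither (edgeR adjusted p of 0.964 and 0.0817). In adipocytes Eif4a2 rose by 0.70 ± 0.09 (edgeR adjusted p = 0.000597), and Kng2 rose from 0.353 ± 0.172 to 13.7 ± 0.423 CPM. On the other side of Adipoq, St6gal1 fell by 1.31 (edgeR adjusted p = 0.0267), Rtp4 fell by 0.53 (edgeR adjusted p = 0.04) and Masp1 rose by 2.89 (edgeR adjusted p = 0.000154) in adipocytes. In liver these 3 genes were at -0.09, 0.22 and -0.37 without passing. Eif4a2 and Rfc4 overlap in the annotation, so reads in the overlap cannot be assigned to either with certainty. Kng1 and Kng2 are close paralogs, and Kng1 held 0 to 20 counts in knockout-labelled adipocyte libraries where Kng2 held 482 to 673. Fetub, upstream of Kng2 and also chosen afterwards, was at 0.15 ± 0.12 in liver without passing (edgeR adjusted p = 0.757) and rose in adipocytes from 0.15 to 0.555 CPM (edgeR adjusted p = 0.00511).

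**Figure D4:**
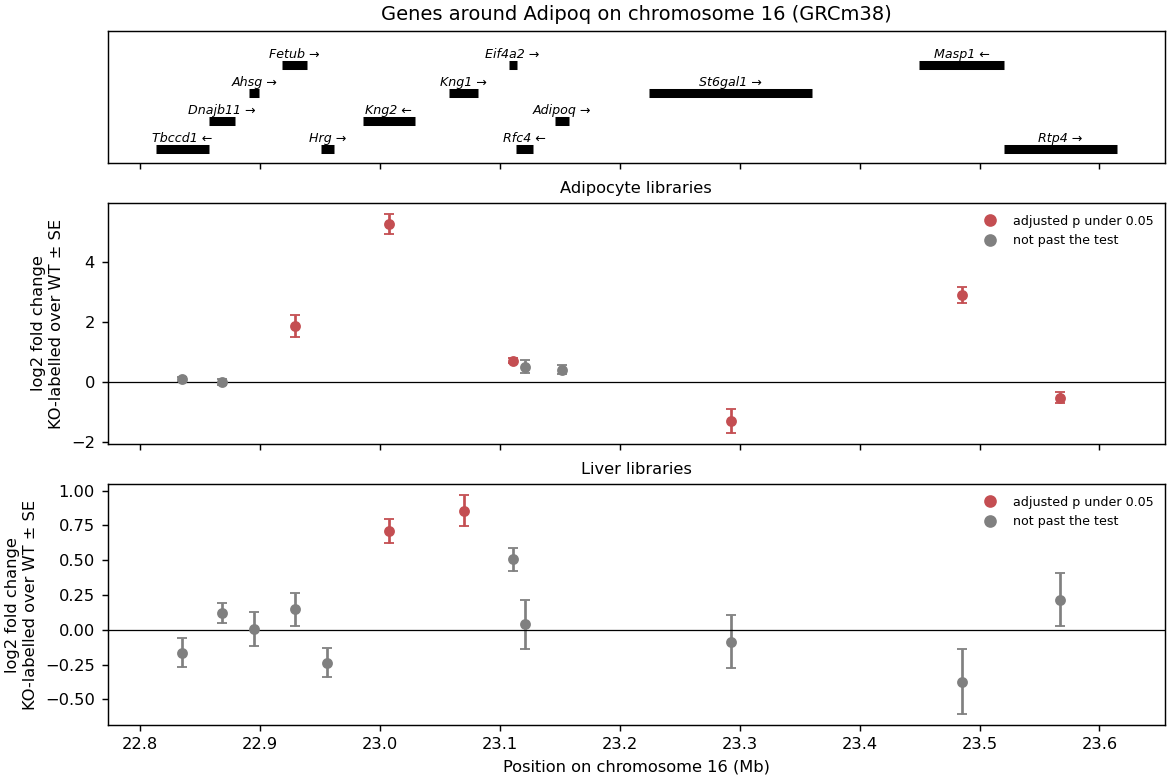
Genes around Adipoq on chromosome 16 of GRCm38 (top, position in Mb), with the log2 fold change of each, knockout-labelled over wild-type, and its SE in adipocyte (middle) and liver (bottom) libraries, n = 4 per group. Red points passed an adjusted p of 0.05, which in liver were Kng1 at 0.85 and Kng2 at 0.71.

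The genotype difference itself differed between the tissues for many genes. Cyp2f2, lower in knockout-labelled adipocytes, differed most clearly, with an adipocyte minus liver difference of -7.92 ± 0.25 (edgeR adjusted p = 3.59e-12). The other 7 genes with the smallest adjusted p were more positive in adipocytes: Kng2 (4.57 ± 0.25), the microtubule-associated Map7 (2.48 ± 0.14), the galactosyltransferase gene B3galt1 (3.83 ± 0.24), Slc15a5 (6.22 ± 0.40), 1100001G20Rik (2.61 ± 0.18), Aadac (6.03 ± 0.43) and Tmem56 (2.98 ± 0.22), with edgeR adjusted p from 1.24e-08 to 4.71e-07. Of 14898 genes edgeR called 2845, with 1544 more positive in adipocytes and 1301 more positive in liver. Scaling by library totals alone moved the median difference by -0.236 and gave 683 and 2242, 23.4% more positive in adipocytes in place of 54.3%. In the mice taken at 76 days 666 genes were called, and without mouse WT-1135, KO-1139 or KO-1151 the counts were 1780, 1798 and 1758.

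Across the 12320 genes tested in both tissues the log2 changes had Pearson r = -0.103 and Spearman rho = -0.0943, a description across genes, which are not independent replicates. Of 124 genes with a liver p under 0.005, 25 were called in adipocytes in the same direction and 22 in the opposite direction. Zfp949 and Kng2 were called in both tissues and were higher in both, with Zfp949 at 1.59 ± 0.16 in adipocytes (edgeR adjusted p = 0.000209), a gene chosen there after its value was seen.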

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

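The tests of stromal cell share, of the genes near Adipoq, of reads shared between Kng1 and Kng2 and of Trib1 beside stromal markers were chosen after the results were seen, and the other tests of this part beforehand. The genotype effect differed between the tissues for 2845 genes, by the interaction test, led by Cyp2f2 (-7.92), Kng2 (4.57), Map7 (2.48), B3galt1 (3.83), Slc15a5 (6.22), 1100001G20Rik (2.61), Aadac (6.03) and Tmem56 (2.98), as adipocyte minus liver log2 differences. Among all 35 splits of the 8 mice into 4 and 4, only the labels (1 of 35) gave 4849 adipocyte calls or more, and the highest other split gave 0. For liver only the labels (1 of 35) gave 3 calls or more, and the highest other split gave 1. For the tissue difference only the labels (1 of 35) gave 2845 or more, and the highest other split gave 43, when mouse WT-1153 and mouse KO-1137 changed places. This share is under the 0.05 set beforehand for all 3 counts. It is also the smallest that these splits can give, and it was not adjusted for the 3 counts. For the adipocyte and tissue-difference counts it argues against chance. In liver it rests on 3 calls against 1, and Kng1 and Kng2 kept their calls only when WT-1136 was the mouse left out. Chance is therefore not excluded for liver. A split that mixes the genotypes holds their difference within its groups, which lowers its own count.

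A library was singled out when its gap to the nearest of the other 3 in its group took most of the group's range. This happened in 56 of 844 groups of 4 tested, where chance gives about 1 in 20, or 42.2. In adipocytes the values were as follows. Mouse WT-1136 stood apart in CPM of Kng2 (0.0969 against 0.414 to 0.464), Bgn (66.8 against 120 to 126), Muc1 (0.702 against 1.58 to 1.74) and Cela1 (17.1 against 10.9 to 11.7). Mouse WT-1153 stood apart in CPM of Gm4841 (55.4 against 16.8 to 22.9), Myl1 (66.1 against 47.7 to 50.7) and Fga (2.24 against 0.569 to 0.727), and in the hepatocyte marker score (2.773 against 1.495 to 1.617). Mouse WT-1135 stood apart in CPM of Retn (841 against 1160 to 1190), Cyp2b13 (0.0387 against 0 to 0), Acer2 (109 against 126 to 130), Nos2 (14.4 against 4.43 to 5.73), Mcm6 (11.6 against 7.31 to 7.63), Itgax (2.24 against 0.776 to 0.975) and Spp1 (2.4 against 0.341 to 0.63). Mouse KO-1152 stood apart in CPM of Dda1 (52.7 against 57.1 to 57.7). Mouse KO-1139 stood apart in CPM of Me1 (3110 against 1900 to 1980), Cd14 (30.5 against 40.8 to 42.8) and Sox9 (3.32 against 5.02 to 5.34), and in the adiponectin receptor score (5.886 against 5.833 to 5.837). Mouse KO-1151 stood apart in CPM of Prkar2b (2320 against 2090 to 2120) and Kdr (38.6 against 68.8 to 73.8). Mouse KO-1137 stood apart in CPM of Mcm6 (6.51 against 4.34 to 4.67) and B3galt1 (33 against 44.7 to 46.4), and in the Tribbles partner score (6.025 against 5.936 to 5.945), the fatty acid oxidation score (6.594 against 6.76 to 6.791), the extracellular matrix score (6.4 against 5.562 to 5.699), the cell-cycle score (0.7691 against 0.495 to 0.5188) and the fibroblast and progenitor score (4.151 against 2.787 to 2.998).

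In liver the values were as follows. Mouse WT-1136 stood apart in CPM of Elovl5 (420 against 282 to 287), Ifit2 (2.26 against 3.06 to 3.09), Arntl (4.08 against 1.42 to 1.87) and Cldn7 (0.133 against 0.289 to 0.319), and in the endothelial score (3.014 against 3.256 to 3.3). Mouse WT-1153 stood apart in CPM of Sqle (46.8 against 27.8 to 30.3), Stat2 (103 against 73.5 to 77.3) and Fabp1 (7790 against 4120 to 4630). Mouse WT-1138 stood apart in CPM of Plin2 (201 against 282 to 299), Cyp7b1 (149 against 345 to 365) and Pecam1 (11.9 against 9.26 to 9.7). Mouse WT-1135 stood apart in the inflammation score (1.448 against 1.988 to 2.05). Mouse KO-1139 stood apart in CPM of Angptl4 (302 against 269 to 273), Cyp2a4 (11.4 against 1.98 to 3.29) and Flt1 (2.78 against 4.03 to 4.16), and in the male-biased score (8.126 against 8.615 to 8.692). Mouse KO-1137 stood apart in CPM of Fgf21 (3.88 against 1.07 to 1.29), Slc2a1 (9.95 against 10.8 to 10.9), Cxcl10 (6.61 against 3.61 to 3.93) and Krt19 (1.74 against 1.05 to 1.11), and in the bile acid score (8.173 against 8.363 to 8.388). Mouse KO-1152 stood apart in CPM of Agpat1 (12.5 against 18.4 to 18.5), Arntl (3.39 against 0.545 to 1.01) and Egfl7 (21.3 against 21.2 to 21.2), and in the adiponectin receptor score (4.521 against 4.595 to 4.608).

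The knockout-labelled adipocyte libraries held lower markers of endothelial, mural and fibroblast cells, and a lower share of such cells may lie behind part of the other changes. Against it as the whole source of the rise of oxidative phosphorylation genes, their score rose above that of adipocyte markers by 0.286 (exact permutation p = 0.0286, n = 4 per group). This p is the smallest such a test can give, and the contrast takes the adipocyte marker list as a measure of adipocyte share. With the marker score as a covariate the median of oxidative phosphorylation genes was 0.301 (median SE 0.193), against 0.551 (0.107) before. Calls went from 45 to 0 as the estimate shrank and its SE grew, so part of the rise stays open. For interferon-stimulated genes it cannot be told apart: with the same covariate their median was -0.694 (median SE 0.372), against -1.17 (0.262) before, since the covariate shared most of its variance with genotype and inflated that of the genotype term 3.97-fold. Nor can a lower share of all other cells together be told apart, since the endothelial and macrophage scores differed by -0.983 at an exact permutation p = 0.143 (n = 4 per group), and a change within the vascular or stromal cells, or in collagenase release, was not tested.

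Kng1 and Kng2, near Adipoq, were higher in the liver of knockout-labelled mice. In edgeR Eif4a2 (0.51), Snora81 (0.925), Rfc4 (0.04) and St6gal1 (-0.09) did not pass, though Eif4a2 and Snora81 did not overlap between the groups. A difference at this place in the genome carried by the knockout-labelled mice is a candidate explanation. The median liver log2 change over 6 consecutive tested genes from Kng2 (Kng2, Kng1, Eif4a2, Snord2, Snora81 and Rfc4) was 0.607. In liver 6 of 12385 such runs, this one included, were as high, with 0.711 the highest elsewhere. The rule, also set afterwards, asked for the highest run of all, so this test cannot decide. Snord2 and Snora81 lie within Eif4a2, so their values are not independent of it. In adipocytes, where Kng1 was not tested and the run reached Adipoq, the median was 0.457, with 330 of 12862 runs as high. Of the genes tested there 35.2% were called, so this share and that of liver are not alike. The start and length of this run were set after its values were seen, and a count of low p-values in windows had been looked at before it, so the share of runs is no unbiased p-value. Reads shared between Kng1 and Kng2 also stay open for the Kng2 call, since the liver ratio of Kng2 to Kng1 moved by -0.15 on the log2 scale with exact permutation p = 0.0571 (n = 4 per group). A response of these genes to the genotype itself was not tested.

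Trib1 totals were not lower in the knockout-labelled adipocyte libraries. A swap of 1 wild-type and 1 knockout-labelled mouse is argued against, since the highest count among the 16 such splits was 0 adipocyte calls. Trib1 counts mainly from the stromal cells are argued against as well, since Trib1 was at 0.28 while the medians of the endothelial, mural and fibroblast lists were -1.86, -1.43 and -1.36. With the marker covariate Trib1 turned to -0.39 (SE 0.244) without passing, so a lower level within the adipocytes stays open. A deletion that leaves most of the transcript countable may fit these values, and so may a reversal of all labels or an incomplete deletion, and none of these 3 was tested.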

How the results depend on the processing

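The halved counts and the marker covariate were chosen after the results were seen, and the other alternatives beforehand. Of adipocyte gene calls the marker covariate cost most, with 437 in place of 4849, and it left 6 lists in place of 23, with a score strongly correlated with genotype. The mice taken at 76 days, 3 wild-type and 2 knockout-labelled, gave 1730 adipocyte, 0 liver and 666 interaction calls, from fewer samples. In liver DESeq2 called 102, no filter 5 and an adjusted p under 0.1 5, and the cause was not tested for DESeq2. No adipocyte call was made in the opposite direction by any alternative, but under the covariate only 381 of the 4849 calls were kept and 598 of these genes turned sign. With an estimated correlation 0 lists were called in either tissue, and fry called 27 in adipocytes and 0 in liver.

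Leave-one-out counts ran from 3553 to 5296 genes in adipocytes, 1 to 3 in liver (1 without KO-1137, WT-1138 or KO-1139) and 1758 to 2988 for the tissue difference (1780 without WT-1135, 1798 without KO-1139, 1758 without KO-1151). Called lists ran from 20 to 24 in adipocytes and from 5 (without KO-1151) to 11 in liver. Of other cell types' scores, 4 passed, 0 with medians, and leave-one-out gave 0 to 5, with 0 without WT-1135, WT-1136, KO-1137, WT-1138, KO-1139, KO-1151 or KO-1152. Such a pass depends on how many lists share the smallest permutation p, so these counts do not show how stable the score differences are. Trib1 ran from 0.13 to 0.40 in adipocytes and from 0.01 to 0.28 in liver, and Adipoq from 0.28 to 0.47. With the covariate Trib1 reversed to -0.39. Adipoq passed with DESeq2 (0.41) and limma-voom (0.42) and fell short with library totals (0.22, adjusted p 0.154). It also fell short in the fit of all 16 libraries, with its estimate kept and a larger SE (0.43 ± 0.5, adjusted p 0.542). With the covariate Adipoq was at 0.0284 (adjusted p 0.974).

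With the mouse as a fixed block 2245 genes were called for the tissue difference, and 2398 with a random block, and the pairing changed no other call named here.

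Of 161 named adipocyte genes past the test, 148 kept their call without each mouse in turn and 13 lost it without at least 1. Among those the text prints, Cd4 was lost without WT-1135, WT-1136, KO-1139, KO-1151 or WT-1153 (adjusted p 0.0508 to 0.0715) and Lck without WT-1135, WT-1136, KO-1139, KO-1151 or KO-1152 (0.0524 to 0.0737). Tpsb2 was lost without WT-1135, WT-1136, KO-1151 or KO-1152 (0.0519 to 0.0592) and Casq1 without WT-1135, KO-1137, WT-1138, KO-1139, KO-1151, KO-1152 or WT-1153 (0.0526 to 0.107). Alas2 was lost without WT-1135, WT-1136, KO-1139, KO-1151 or KO-1152 (0.0804 to 0.108). So were Sox9 without KO-1151 or KO-1152 (0.0585 and 0.0634) and Hsd3b7 without KO-1151 (0.0539). Mcm6 was lost without KO-1139 (0.0518), and Mcpt4 without WT-1135, WT-1136, KO-1139, KO-1151 or KO-1152 (0.0542 to 0.0751). Myl1 was lost without WT-1135, WT-1136, WT-1138, KO-1139, KO-1151 or KO-1152 (0.0863 to 0.129). Short of the threshold with all mice, but past it with a mouse left out, were Ctss without KO-1137 (0.00523), Foxo1 without KO-1137 or WT-1153 (0.0448 and 0.0485), Trp63 without KO-1137 or WT-1153 (0.0225 and 0.0314). So did Spp1 without KO-1151 or WT-1153 (0.0423 and 0.037), Cela1 without WT-1136 (0.0438) and Rfc4 without KO-1151 (0.0305). Dda1 and Muc1 passed without WT-1136 (0.0344 and 0.0292), Lyz2 without KO-1137 (0.00957) and Nfil3 without KO-1137 or WT-1153 (0.0349 and 0.0112). Some of these also passed in other fits. In liver the same was seen for Elovl6 without KO-1152 (0.0423), Acacb without WT-1135 (0.0316), 9130409I23Rik without KO-1151 (0.0422) and Robo1 without WT-1153 (0.0222), which DESeq2 called as well. Under the covariate 101 named adipocyte genes lost the call with their sign kept, 60 kept sign and side of the threshold, and 16 turned sign, whether called before or not. In the mice taken at 76 days 41 no longer passed. DESeq2 called 27 more of the named liver genes.

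Signs turned for named genes as follows, the cause not being tested unless it is stated. With the covariate in adipocytes the values became Trib2 0.18, Ero1l -0.24, Hspa5 -0.13, Foxo1 -0.32, Hspb1 0.17, Nfil3 -0.41, Itgax 0.0463, Lyz2 0.61, Ctss 0.37, Mcpt4 0.0323, Acta2 0.0721, Notch3 0.39, Myl1 -0.0624, Alas2 0.26, Pdgfrb 0.35 and Dcn 0.0224. Acta2, Notch3, Pdgfrb and Dcn are members of the lists behind the covariate, so the loss of their fall is built into that fit. With library totals the values were Dda1 -0.0151 and Ero1l -0.0535. In liver, where none of these genes passed, the mice taken at 76 days gave Bhlhe40 -0.0296, Neb 0.04, Eno3 0.19, Casq1 0.29, Cela1 0.0507, Cyp2f2 -0.0612, 1100001G20Rik 0.0416 and Rfc4 -0.0811. Library totals gave Eno3 0.00997, 1100001G20Rik 0.00346 and Aadac 0.00415 in liver. The age term gave 1100001G20Rik 0.0114, and limma-voom gave Casq1 0.27. Leave-one-out ranges that crossed 0 in liver were Got1 -0.46 to 0.0338, Mylpf -0.0785 to 0.41, Neb -0.11 to 0.0787, Eno3 -0.15 to 0.0807 and Casq1 -0.52 to 0.23. They were also Cela1 -0.20 to 0.18, Cyp2f2 -0.0217 to 0.14, 1100001G20Rik -0.0728 to 0.0482, Aadac -0.0572 to 0.0472 and Rfc4 -0.0539 to 0.14. Depth did not limit the named genes with means above 1 CPM in both groups. It limits Rasef, Cyp2b9, Cyp2b13, Aadac, Acot3, Acot5 and Chodl, whose wild-type counts were near 0, and Ngfr, whose knockout-labelled counts were. Gm9696 (0.127 CPM), Bmpr1b (0.148) and Fetub (0.15) in wild-type and H19 (0.128) in knockout-labelled adipocyte libraries were also low. No interval was computed for them.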

Other observations

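Several adipocyte lists held genes that passed the edgeR test in both directions and were not called by camera. Of all tested adipocyte genes 35.2% were called, 2487 higher and 2362 lower. Called members in both directions therefore do not by themselves set a list apart from other genes. Fry, also set beforehand, called 6 of the lists given here: xenobiotic (adjusted p = 0.00301), cell cycle (0.00967), skeletal muscle (0.0116), adiponectin receptors and AMPK (0.0124), Tribbles partners (0.0276) and lipoprotein genes (0.0315). Fry does not compare a list with the other genes, so these passes do not set the lists apart from them. The lists and both list tests were fixed beforehand, while the marker covariate was chosen after the results were seen. With it calls went from 12 to 5 for thermogenic (median 0.244 to -0.206) and from 11 to 1 for lipoprotein genes (0.225 to -0.341). For cell-cycle genes they went from 8 to 0 (-0.594 to -0.109). The medians of secreted factors (-0.106 to -0.1) and clock genes (-0.222 to -0.252) changed little, with fewer calls. Of 19 thermogenic genes 7 rose and 5 fell (7 and 6 adjusted over the list alone), led by the potassium channel gene Kcnk3 (0.86 ± 0.08) and Elovl3 (4.49 ± 0.46), with camera adjusted p = 0.354. Of 8 xenobiotic genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), led by Cyp2b9 and Cyp2b10 (3.84 ± 0.34), with camera adjusted p = 0.0886. Of 18 secreted factors 3 rose and 4 fell (4 and 4 adjusted over the list alone), with the chemerin gene Rarres2 at -1.99 ± 0.18 and Retn at 1.27 ± 0.14 (camera adjusted p = 0.982). Of 12 genes for adiponectin receptors and AMPK 2 rose and 3 fell (2 and 4 adjusted over the list alone), with the ceramidase gene Acer2 at -0.56 ± 0.09 and the AMPK subunit gene Prkab2 at -0.62 ± 0.12 (camera adjusted p = 0.545). Of 10 adiponectin assembly genes only Pparg rose (1 adjusted over the list alone), and Foxo1 was at 0.37 ± 0.15 without passing (camera adjusted p = 0.346). Of 10 Tribbles genes and partners Rfwd2, the ubiquitin ligase COP1, rose (0.55 ± 0.09), Trib3 rose (0.65 ± 0.17) and Trib2 fell (-1.66 ± 0.37), with the same 2 and 1 adjusted over the list alone (camera adjusted p = 0.442). With the marker covariate Trib2 turned to 0.18 (edgeR adjusted p = 0.828) and Rfwd2 was at 0.30 without passing (0.352). That left 1 call in this list in place of 3. Trib3 did not pass in edgeR with library totals (adjusted p = 0.0894), in the mice taken at 76 days (0.0625) or with all 16 libraries in the fit (0.0705).

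Of 20 lipoprotein genes 8 rose and 3 fell (8 and 3 adjusted over the list alone), led by Apoc2 (2.30 ± 0.23) and Apoc3 (1.59 ± 0.29), with camera adjusted p = 0.103. Of 6 bile acid genes Cyp27a1 rose (1.83 ± 0.13) and Abcb4 (-1.59 ± 0.38) and Hsd3b7 (-0.28 ± 0.07) fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.538). Of 17 clock genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), led by Hlf (-1.79 ± 0.27) and Bhlhe40 (0.53 ± 0.08), with camera adjusted p = 0.407. Of 21 cell-cycle genes 1 rose and 7 fell (1 and 7 adjusted over the list alone), led by Ccne1 (0.69 ± 0.14) and Mcm2 (-0.89 ± 0.21), with camera adjusted p = 0.0504. Granulocyte markers (2 higher and 2 lower of 11, with S100a8 at 1.64 ± 0.42 and Tpsb2 at -1.61 ± 0.45), skeletal muscle markers (1 and 2 of 10, with Acta1 at -1.73 ± 0.31 and Casq1 at -1.75 ± 0.60) and Schwann cell markers (1 and 2 of 11, with S100b at -1.17 ± 0.22 and Cdh19 at -1.3 ± 0.28) had camera adjusted p of 0.85, 0.254 and 0.2. Adjusted over the list alone these counts were 3 and 2, 0 and 1, and 1 and 2. Too few members were tested for epithelial markers (Trp63 at 0.60 ± 0.26, not passing), red cell markers (Alas2 at -1.04 ± 0.34, lower), cholangiocyte markers (Sox9 at 0.75 ± 0.22, higher, and Spp1 at -1.91 ± 0.71, not passing) and pancreas markers (Cela1 at 0.24 ± 0.17, not passing).

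In liver the lists not called and not yet given had these camera adjusted p values, with no member past the edgeR test: Tribbles partners 0.903, adipocyte markers 0.903, secreted factors 0.143, adiponectin assembly 0.943, adiponectin receptors and AMPK 0.582, triglyceride synthesis 0.903, lipolysis 0.128, thermogenic 0.582, oxidative phosphorylation 0.59, insulin and glucose use 0.943, gluconeogenesis 0.582, female-biased genes 0.179, stress response 0.125, immediate early 0.432, inflammation 0.107, clock 0.903, matrix 0.582, cell cycle 0.943, lymphocytes 0.238, fibroblasts 0.675, mural cells 0.943, epithelium 0.779, Schwann cells 0.432, hepatocytes 0.59, stellate cells 0.773 and cholangiocytes 0.331. DESeq2 called members of some of them, among them Cd36 (adjusted p = 6.8e-05), Hspa1b (0.00545), Atp6v0d2 (0.00762), Hyou1 (0.0229), Pfkfb3 (0.0315) and Creld2 (0.0337). Skeletal muscle, red cell and pancreas lists held 4, 1 and 2 tested liver genes and were not tested.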
